A study of Mus musculus with 13 samples.

How the data were processed

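RNA from the medial prefrontal cortex of 13 adult C57BL/6J mice was measured on Affymetrix Clariom S Mouse arrays, which carry 1 colour and read most genes with a single probe set. The mothers had received saline or 20 mg/kg of poly(I:C), a synthetic double-stranded RNA that mimics a virus, at embryonic day 12.5. The offspring were 4 months old. The poly(I:C) group held 5 samples, labelled 2 male and 3 female, and the saline group held 8, labelled 4 male and 4 female. The labels call the samples biological replicates and name neither dam nor litter, so the p-values treat each animal as independent of its littermates. The number of arrays limits the precision.

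The deposited values are log2 expression levels, 1 per probe set and array. Per the submitters' processing notes, the authors used the Transcriptome Analysis Console with RMA, a procedure that subtracts background, makes the distributions of all arrays alike and summarises the probes of each probe set, and limma for testing. Their versions are not given in the sources used here. Making distributions alike hides any change shared by most genes. Values ran from 1.85 to 19.7, and the median over gene probe sets lay between 6.36 and 6.45 in each array. A scanner range of 16 bits ends at 16 on the log2 scale, so a rescaling is part of the deposited values, and its form is unknown here. Levels of 1 probe set were therefore compared between arrays, and levels of different probe sets were not compared with each other, except that a probe set was called above background in an array when it exceeded the median of the negative controls there.

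The table held 28846 probe sets. Of these, 6640 controls were left out of the tests and 22206 gene probe sets were kept, with no filter on low values. Names came from the platform's annotation, brought up to date through gene identifiers of the mouse assembly GRCm38.p6, which changed 0 symbols. A single symbol was given for 19572 probe sets, several for 0, and 2634 are unnamed here. The named probe sets covered 19505 genes, 55 of them with more than 1 probe set. For gene lists, the probe set with the highest mean over all 13 arrays stood for a gene. No genome build is named in the sources used here, and no coordinates are printed. Xist and Ddx3y were not analysed here.

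Tests were made with limma 3.58.1 in R 4.3.3, as two-sided moderated tests with lmFit and eBayes and Benjamini-Hochberg adjustment over the 22206 probe sets, at an adjusted p of 0.05 with no minimum fold. Maternal treatment was tested with labelled sex as a term. The contrasts within each labelled sex and their difference came from a fit with 4 cell means. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. An exact permutation test, two-sided, compared the mean level of each list over all 1287 splits of the samples into 5 and 8. Benjamini-Hochberg adjustment covered the 45 lists with at least 4 measured genes, out of 46 written. The designs, the lists, the alternatives named as planned and the rule for naming genes were fixed before the data were examined. The lists held 1048 genes, of which 906 were measured. Among the 45 lists, 18 hold markers of cell types or of neighbouring regions that a dissection can carry along.

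The genes named are the 15 largest rises and the 15 largest falls past the threshold, the 5 smallest p-values of each contrast within a labelled sex and of their difference, the 5 largest changes in each direction between the labelled sexes, the Y-linked genes, and up to 4 members of each list with the largest moderated statistic.

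Looking at the arrays showed that saline replicates 5 to 8 differ from the other 9 arrays in control probe sets that do not come from the tissue. A comparison of the 5 poly(I:C) arrays with saline replicates 1 to 4 alone, 9 arrays in all, was therefore added after the data were seen, and its values stand beside those of all 13 arrays. That comparison has no sex term. Saline replicates 1 to 4 are all labelled female, so such a term would rest on the poly(I:C) arrays alone. By Y-linked level, 3 of the 5 poly(I:C) libraries are male and saline replicates 1 to 4 are all female, so sex is not balanced there. A Y-linked term is reported in the 9 arrays for the ribosomal list only. An exact permutation test there runs over 126 splits. The exact permutation test over 13 arrays has no term for sex or array set, so an offset of saline replicates 5 to 8 enters its p. For other added settings, the mean level of the Y-linked genes replaced labelled sex, or the libraries whose Y-linked level opposes the label were left out. Other settings, fixed in advance, changed the normalization, filter, variance prior, array weights, threshold, covariates, replicate block, list test and probe choice, and left out each array in turn.

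The gene test was checked on simulated data with the spread of these arrays and 50 probe sets changed at each of 4 sizes among 22206. It recovered 2% of them at a log2 change of 0.3, 18% at 0.5, 64% at 1 and 100% at 2, with 8 false calls. For the list test, the ribosomal list was simulated 100 times with no effect and noise shared by all its genes in an array (SD 0.3). The unadjusted p was under 0.05 in 73 cases with the preset correlation and in 5 with an estimated correlation. The measured SD of this list mean was 0.314 in poly(I:C), 0.077 in saline replicates 1 to 4 and 0.113 in 5 to 8. The 73 cases belong to that noise and that list. The gene counts for treatment, for treatment within labelled females and for labelled sex, and the list counts for treatment in 13 and in 9 arrays, were also compared with up to 100 splits of the same samples, the real one included. For treatment genes, splits that keep saline replicates 5 to 8 in the group of 8 were added after the data were seen. The counts within labelled males and for the difference between the sexes were not, since they rest on 2 poly(I:C) libraries labelled male.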

Results

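Gene expression was measured in the medial prefrontal cortex of 13 adult mice, 4 months old, whose mothers were injected during pregnancy with poly(I:C) or saline. The question was which transcripts still differ in adult offspring after the mother's immune response to a viral mimic. The poly(I:C) group held 5 arrays and the saline group 8, and 22206 gene probe sets were tested. The median level per array lay between 6.36 and 6.45 on the log2 scale.

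Transcripts of the Y chromosome did not follow the sex labels in the poly(I:C) group. The mean log2 level of Kdm5d, Eif2s3y and Uty, the 3 Y-linked genes measured, lay between 8.09 and 8.73 in the 4 saline libraries labelled male, and it was at most 3.27 in the 4 labelled female. In the poly(I:C) group, the level was 8.81 in the library labelled male replicate 1 and 3.01 in the library labelled female replicate 2, as in saline libraries of the same label. It was 8.63 and 8.37 in the libraries labelled female replicates 3 and 4, and 3.19 in the library labelled male replicate 5. Thus 3 of 5 poly(I:C) libraries and 0 of 8 saline libraries opposed their label. Sex below means the label.

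**Figure D1:**
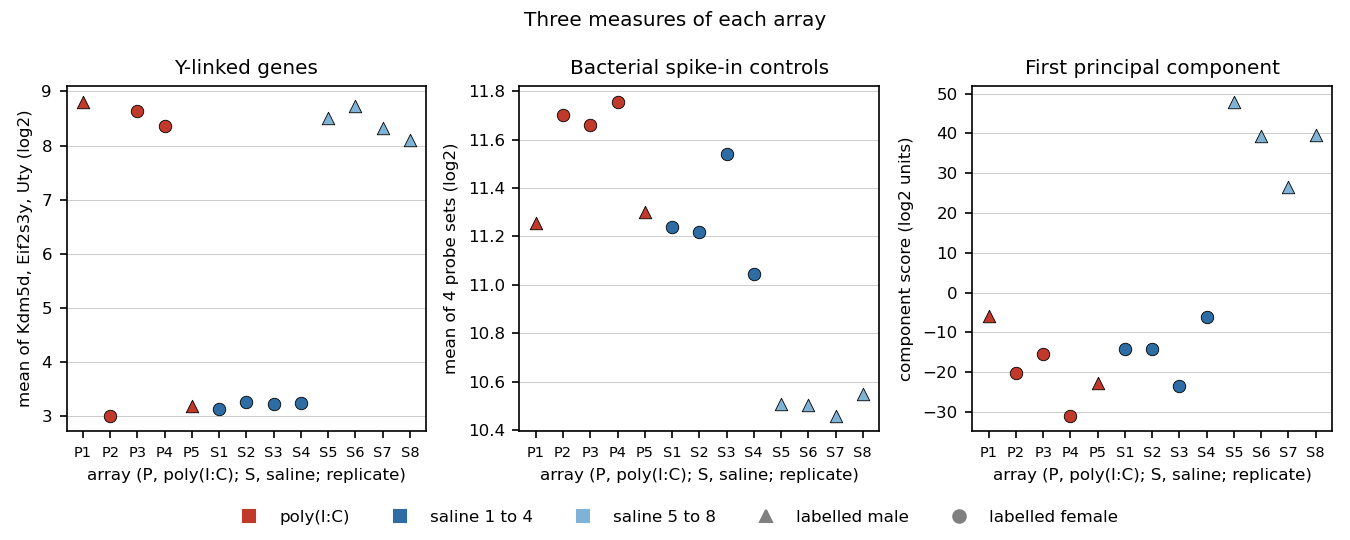
Mean log2 level of 3 Y-linked genes (left), mean log2 level of 4 bacterial spike-in probe sets (middle) and score on the first principal component (right) for each of the 13 arrays. Colours mark poly(I:C), saline replicates 1 to 4 and saline replicates 5 to 8, and triangles mark libraries labelled male; saline replicates 5 to 8 have component scores of 26.5 to 48.0, against -30.9 to -5.86 in the other 9 arrays.

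Saline replicates 5 to 8, which are all the saline libraries labelled male, stood apart from the other 9 arrays. The bacterial spike-in controls, added to the sample and not part of the tissue, averaged 10.51 ± 0.036 (SD, n = 4) in these arrays and 11.41 ± 0.256 (SD, n = 9) in the others, a log2 difference of -0.909 (exact permutation p = 0.0014, the smallest that 715 splits allow). The median of the negative control probe sets was 4.66 ± 0.038 (SD, n = 4) against 4.99 ± 0.128 (SD, n = 9), also with an exact permutation p of 0.0014. The first principal component held 29.2% of the variance and separated the same 4 arrays. Correlations across genes were 0.993 to 0.995 among these 4 arrays and 0.984 to 0.992 between them and the others. The spike-in controls also varied within the 9 arrays, with 11.54 ± 0.237 (SD, n = 5) in poly(I:C) and 11.26 ± 0.207 (SD, n = 4) in saline replicates 1 to 4 (exact permutation p = 0.0952). No poly(I:C) library lay among saline replicates 5 to 8, so values for poly(I:C) against saline replicates 1 to 4 are given beside those for all 13 arrays for the gene lists and for part of the genes, and the plot of changes has them for all 30 genes of the treatment comparison.

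Genes of protein synthesis led the rises in poly(I:C) offspring when all 13 arrays were fitted with labelled sex as a term. Rps19, a protein of the small ribosomal subunit, averaged 12.52 ± 0.505 (SD, n = 5) in poly(I:C) and 11.25 ± 0.434 (SD, n = 8) in saline on the log2 scale, a rise of 1.21 ± 0.18 (SE, limma adjusted p = 0.00905). Rps21 rose by 1.12 ± 0.17, Rps20 by 1.07 ± 0.17, Rpl37rt by 1.05 ± 0.15, Rpl22l1 by 1.05 ± 0.18, Rpl37a by 1.00 ± 0.14, Rpl37 by 0.97 ± 0.15, Rps9 by 0.96 ± 0.16 and Rps28 by 0.94 ± 0.15 (adjusted p from 0.00905 to 0.0122). Eif3f, a subunit of the translation initiation factor that recruits ribosomes, rose by 0.92 ± 0.13 (adjusted p = 0.00905). The other rises named by the rule were Metrn, a secreted glial factor, at 1.21 ± 0.19, Mllt6 at 0.99 ± 0.17, the microRNA gene Mir692-3 at 0.96 ± 0.16, Zbbx at 0.95 ± 0.15, and Gng13, a G protein subunit, at 0.92 ± 0.18 (adjusted p from 0.00905 to 0.0251).

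Among the falls, Egr1, a transcription factor induced by neuronal activity, had the lowest estimate at -1.25 ± 0.26 (SE, adjusted p = 0.0323), with 13.10 ± 0.693 (SD, n = 5) in poly(I:C) and 14.38 ± 0.416 (SD, n = 8) in saline. Chrm4, a muscarinic acetylcholine receptor, fell by 1.25 ± 0.27 (adjusted p = 0.0413). L1cam, a neuronal adhesion molecule, fell by 1.15 ± 0.26, and Vgf, a secreted neuropeptide precursor induced by activity, fell by 0.85 ± 0.16 (adjusted p = 0.0470 and 0.0236). Cx3cl1, the neuronal chemokine whose receptor is on microglia, fell by 0.81 ± 0.17 (adjusted p = 0.0364). Midn, at -1.04 ± 0.22, Actn1, an actin crosslinker, at -0.97 ± 0.21, Mest, an imprinted gene, at -0.84 ± 0.17, and Kif20a, a mitotic kinesin, at -0.84 ± 0.15, also passed (adjusted p from 0.0169 to 0.0367). The remaining falls were Gm11149 at -1.10 ± 0.24, Myadm at -0.88 ± 0.14, the splicing factor Sf3a2 at -0.81 ± 0.15, Tmem145 at -0.78 ± 0.14, Jph2 at -0.78 ± 0.15 and the protocadherin Pcdhb20 at -0.77 ± 0.15 (adjusted p from 0.00919 to 0.0431). Kif20a exceeded the negative-control median in 0 of 5 poly(I:C) and 1 of 8 saline arrays and Jph2 in 0 and 4, so the size of their change is not determined.

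In all, 200 probe sets passed, 151 higher and 49 lower in poly(I:C), and 119 and 44 of them have a gene name here. Between the saline sets, replicates 5 to 8 against 1 to 4, 3050 probe sets passed, 1431 higher and 1619 lower, and 103 of the 200 treatment calls are among them. Of the 151 rises, 33 belong to the fixed list of cytosolic ribosomal proteins. The 200 calls did not pass within the 9 arrays that leave out saline replicates 5 to 8, though 182 had an unadjusted limma p under 0.05. There, limma called 0 of 22206 probe sets against saline replicates 1 to 4, with a smallest adjusted p of 0.534, and 1877 had an unadjusted p under 0.05 where 1110 are expected by chance. With saline replicates 5 to 8 as a batch term the count was also 0 (2295 unadjusted), and without a sex term it was 0 (3536 unadjusted). Leaving out 1 array at a time gave 36 to 512 calls in the 13-array fit.

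All 200 calls kept their sign in the 9 arrays, which share the 5 poly(I:C) and 4 of the 8 saline libraries with the larger fit and so are not independent of it. The median size of their change was 0.74 in 13 arrays and 0.51 in 9. In the 9 arrays Rps19 differed by 0.93 ± 0.22 (SE), Egr1 by -1.01 ± 0.29, Chrm4 by -0.95 ± 0.30, Zbbx by 1.02 ± 0.16, Mllt6 by 0.91 ± 0.24 and Gng13 by 0.88 ± 0.24, each with an adjusted p of 0.534 except Chrm4 at 0.542. L1cam differed by -0.46 ± 0.31 there, Cx3cl1 by -0.37 ± 0.19 and Tmem145 by -0.35 ± 0.14, less than 0.5 of their size in 13 arrays.

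**Figure D2:**
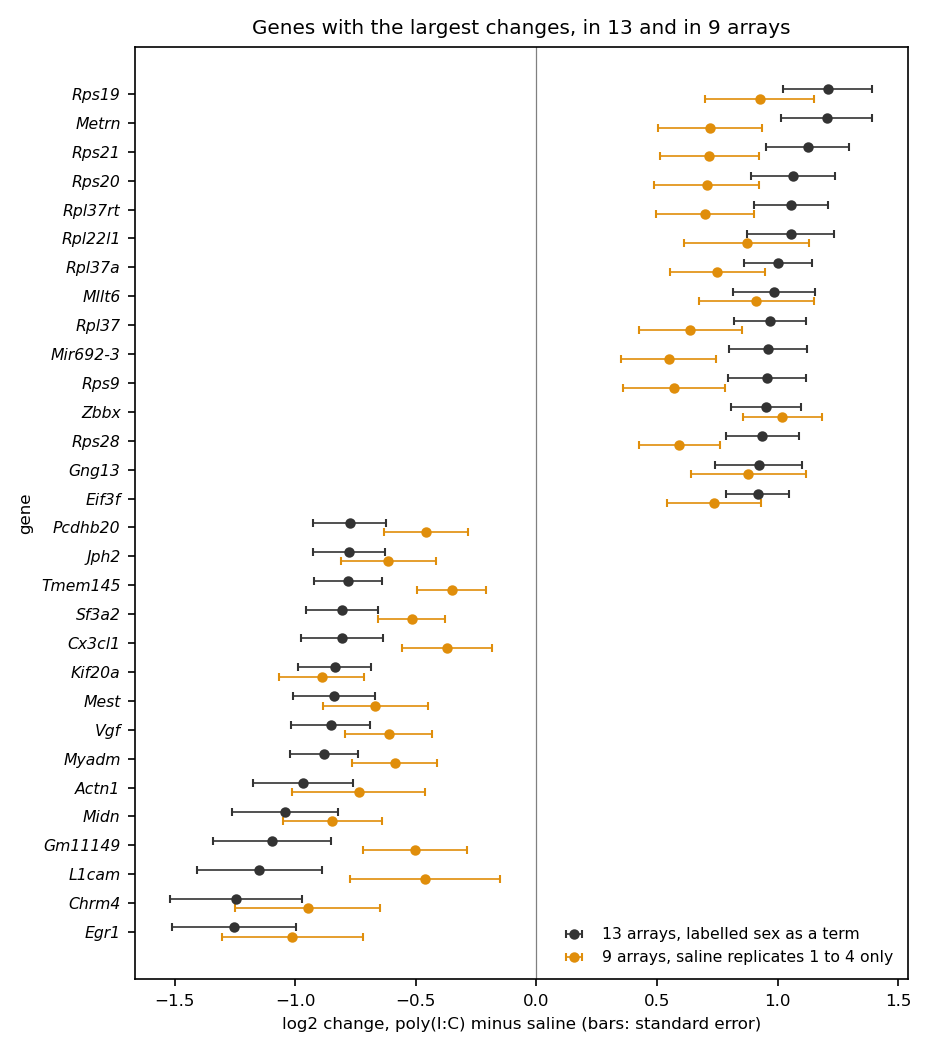
Log2 change, poly(I:C) minus saline, of the 30 genes named for this comparison (vertical axis), with standard errors as bars, in all 13 arrays with labelled sex as a term (dark) and in 9 arrays with only saline replicates 1 to 4 (orange). All 30 genes lie on the same side of 0 in both, and most are nearer to 0 in 9 arrays; Rps19 moves from 1.21 to 0.93 and L1cam from -1.15 to -0.46.

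Ribosomal protein genes moved together. All 55 measured members of the cytosolic ribosomal list had higher estimates in poly(I:C), and 33 rose past the threshold over all genes and 54 when adjusted over the list alone, with 0 falling. Rpl37a rose by 1.00 ± 0.14 (SE), Rpl11 by 0.91 ± 0.13, Rpl7a by 0.82 ± 0.12 and Rps21 by 1.12 ± 0.17. The list mean was 14.79 ± 0.314 (SD, n = 5) in poly(I:C), 14.30 ± 0.077 (SD, n = 4) in saline replicates 1 to 4 and 13.86 ± 0.113 (SD, n = 4) in saline replicates 5 to 8. It lay above every saline array in 4 of 5 poly(I:C) arrays. The median change was 0.69 (camera adjusted p = 2.37e-56), and the adjusted p was 0.134 with an estimated correlation. The exact permutation test, with no term for sex or array set, gave p = 0.00311 (adjusted 0.028) over 13 arrays. In 9 arrays the median was 0.50 with 54 of 55 members higher and 39 adjusted over the list alone (camera adjusted p = 7.36e-34, and adjusted p = 0.346 with an estimated correlation). The exact permutation test there gave p = 0.0397, which is 0.162 after adjustment.

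Genes of the respiratory chain, which makes ATP in mitochondria, were higher too. For complex I, 36 of 36 measured members had higher estimates, 2 rose past the threshold over all genes and 15 adjusted over the list alone. For complexes II to V, 34 of 38 had higher estimates, 7 rose over all genes and 21 adjusted over the list alone. Ndufa6 rose by 0.61 ± 0.12 (SE), Ndufa2 by 0.65 ± 0.13, Atp5k by 0.60 ± 0.11, Cox7a2 by 0.73 ± 0.14 and Cyc1 by 0.62 ± 0.12 (adjusted p from 0.0206 to 0.0292). Median changes were 0.28 and 0.30 (camera adjusted p = 1.19e-13 and 1.16e-15), with an adjusted p of 0.134 for each with an estimated correlation. In 9 arrays the medians were 0.22 and 0.25 (camera adjusted p = 1.69e-08 and 8.67e-10, and adjusted p = 0.346 for each with an estimated correlation). Each list mean lay above every saline array in 4 of 5 poly(I:C) arrays.

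Immediate early genes, which neuronal activity switches on, were lower in poly(I:C). Of 30 measured members, 28 had lower estimates, 1 fell past the threshold over all genes and 17 adjusted over the list alone. Besides Egr1, Fosb had an estimate of -1.95 ± 0.51 (SE), Per1 of -1.23 ± 0.29 and the synaptic pentraxin Nptx2 of -1.08 ± 0.26, none past the threshold over all genes (adjusted p from 0.0539 to 0.0737). The list mean was 9.23 ± 0.531 (SD, n = 5) against 10.05 ± 0.413 (SD, n = 8), below every saline array in 4 of 5 poly(I:C) arrays. The median change was -0.85 (camera adjusted p = 8.39e-11), with an adjusted p of 0.214 with an estimated correlation. In 9 arrays it was -0.71 (camera adjusted p = 9.99e-10, adjusted p = 0.348 with an estimated correlation, exact permutation p = 0.0794).

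Heat shock and protein folding genes had a median of -0.27 in 13 arrays and in 9 (camera adjusted p = 0.000868 and 0.000187, with 0.216 and 0.346 as the adjusted p with an estimated correlation). Of 23 members, 0 fell over all genes and 3 adjusted over the list alone, and the chaperone Hspa5 had an estimate of -0.58 ± 0.15 (SE). In the list mean, 3 of 5 poly(I:C) arrays lay below all 8 saline arrays and 5 of 5 below saline replicates 1 to 4.

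The list of perineuronal net and extracellular matrix genes, which coat neurons and fill the space between cells, had a mean of 7.11 ± 0.094 (SD, n = 5) in poly(I:C), 7.30 ± 0.058 (SD, n = 4) in saline replicates 1 to 4 and 7.31 ± 0.075 (SD, n = 4) in saline replicates 5 to 8. All 5 poly(I:C) arrays lay below all 8 saline arrays (exact permutation p = 0.000777, adjusted 0.0175). In 9 arrays the exact permutation p was 0.0159, and 0.119 after adjustment. The median change was -0.23 in 13 arrays and -0.19 in 9 (camera adjusted p = 0.00325 and 0.00129, with 0.134 and 0.346 as the adjusted p with an estimated correlation). No member passed over all genes or adjusted over the list alone, with Vcan, a proteoglycan, at -0.37 ± 0.12 (SE). Has1, a hyaluronan synthase, exceeded the negative-control median in 0 arrays. Vcan and Tnr are also in the list of oligodendrocyte precursor markers, so the results of these lists are not independent.

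Markers of oligodendrocyte precursors, the cells that give rise to myelinating glia, showed the same separation. Their mean was 8.66 ± 0.030 (SD, n = 5) in poly(I:C), 8.86 ± 0.049 (SD, n = 4) in saline replicates 1 to 4 and 8.91 ± 0.053 (SD, n = 4) in saline replicates 5 to 8, with all 5 poly(I:C) arrays below all 8 saline arrays (exact permutation p = 0.000777, adjusted 0.0175). The median change was -0.19 (camera adjusted p = 0.0162, adjusted p = 0.134 with an estimated correlation). Of 15 members, 0 fell over all genes and 2 adjusted over the list alone, and Sox10 had an estimate of -0.63 ± 0.18 (SE). In 9 arrays the median was -0.16 and the list missed the threshold (camera adjusted p = 0.0526, and 0.346 with an estimated correlation). At the preset correlation it passed without poly(I:C) replicate 4 (adjusted p = 0.021) or saline replicate 3 (adjusted p = 0.0354). Over the 9 arrays the exact permutation p was 0.00794, the smallest that 126 splits allow, and 0.119 after adjustment.

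**Figure D3:**
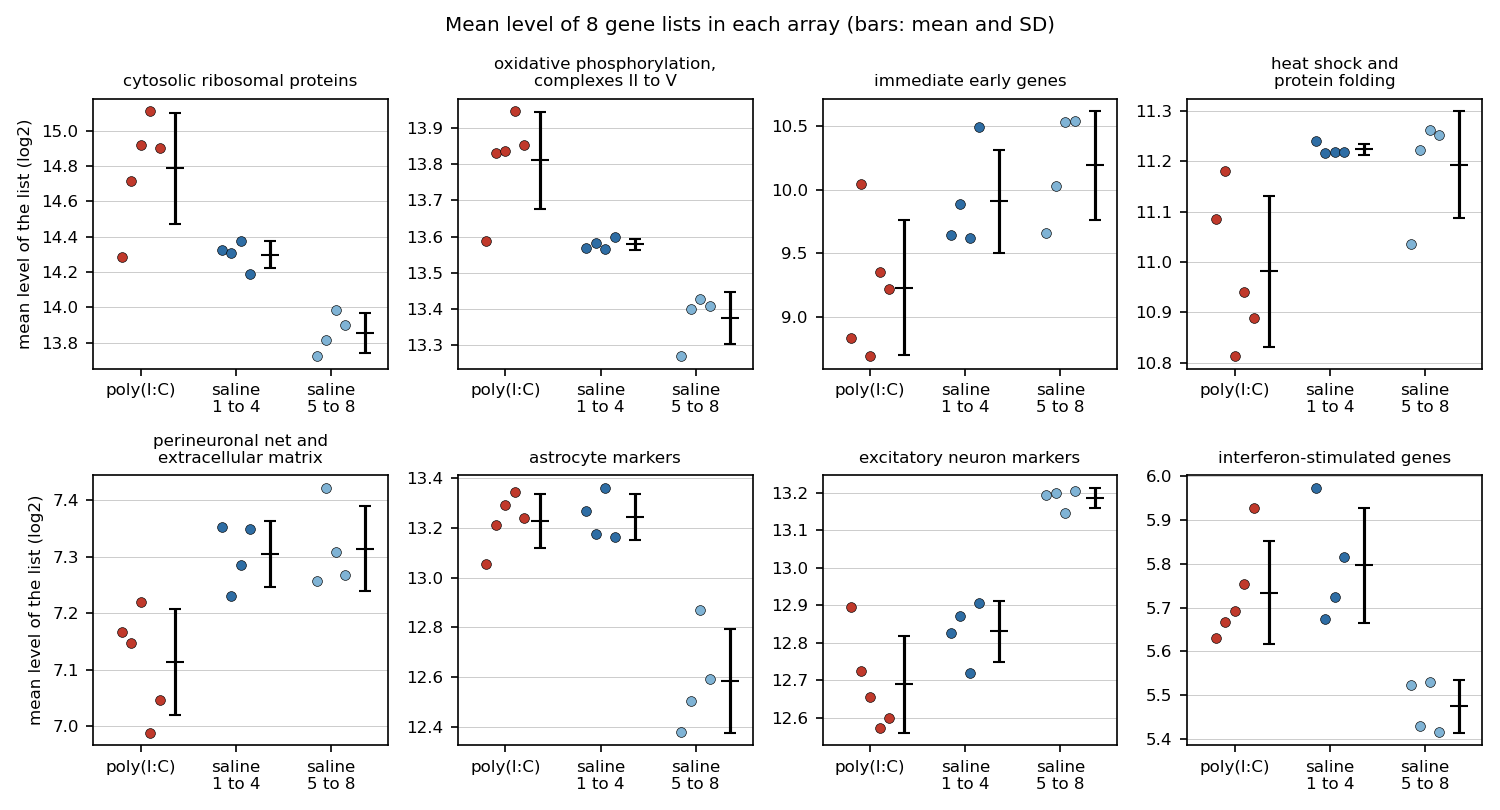
Mean log2 level (vertical axis) of 8 gene lists in each array, by poly(I:C), saline replicates 1 to 4 and saline replicates 5 to 8, with the mean and SD of each set beside its points. Ribosomal protein genes average 14.79, 14.30 and 13.86 in these sets, while astrocyte markers average 13.23, 13.24 and 12.59.

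The other called lists passed in 13 arrays and not in the 9. Astrocyte markers had a median of 0.22 in 13 arrays (camera adjusted p = 0.000213, adjusted p = 0.42 with an estimated correlation) and 0.03 in 9 (camera adjusted p = 0.949, with the test leaning lower while the median is above 0), and they were lower in saline replicates 5 to 8 than in 1 to 4, with a median of -0.75 (camera adjusted p = 2.08e-07). Gfap, the astrocyte filament protein, was at 11.98 ± 0.475 (SD, n = 5) in poly(I:C), 11.77 ± 0.286 (SD, n = 4) in saline replicates 1 to 4 and 9.64 ± 0.226 (SD, n = 4) in saline replicates 5 to 8. Microglia markers had a median of 0.35 in 13 arrays and 0.09 in 9 (camera adjusted p = 2.49e-05 and 0.0961), oxidative stress response genes 0.23 and 0.08 (adjusted p = 3.14e-06 and 0.0946), and histone genes 0.22 and 0.11 (adjusted p = 0.00624 and 0.212). With an estimated correlation, the adjusted p was 0.134 for each of these 3 lists in 13 arrays. Over all genes 0 astrocyte, 0 microglia, 2 oxidative stress and 0 histone members rose, against 3, 9, 9 and 2 adjusted over the list alone. Of the oxidative stress list, Ftl1, a ferritin subunit, rose by 0.89 ± 0.14 (SE) and the peroxidase Gpx4 by 0.54 ± 0.12.

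Of the other called lists, 5 neuronal ones showed the opposite sign, while upper-layer cortical markers, not called, had a median of 0.15 in 13 arrays. Excitatory neuron markers had a median of -0.32 in 13 arrays and -0.16 in 9 (camera adjusted p = 0.000213 and 0.0961), neuropeptides -0.26 and -0.11 (adjusted p = 0.000539 and 0.105), glutamate receptors -0.22 and -0.06 (adjusted p = 0.0243 and 0.863), presynaptic vesicle genes -0.21 and -0.06 (adjusted p = 0.0149 and 0.949), and somatostatin, VIP and other interneuron markers -0.15 and -0.01 (adjusted p = 0.0424 and 0.925). With an estimated correlation, the adjusted p in 13 arrays was 0.155, 0.216, 0.455, 0.478 and 0.478 in that order. Over all genes 1 member of these 5 lists fell, the neuropeptide precursor Vgf, and adjusted over the list alone 6, 4, 2, 6 and 1 fell in the same order, with 1 presynaptic gene rising. All 5 were higher in saline replicates 5 to 8 than in 1 to 4, with medians from 0.27 to 0.42 (camera adjusted p from 6.02e-05 to 0.00974). Nptx1 had an estimate of -0.60 ± 0.16 (SE) and the glutamate receptor subunit Grin2b one of -0.77 ± 0.19 in 13 arrays, and -0.32 ± 0.16 and -0.25 ± 0.19 in 9. With 8 of the 9 arrays and the preset correlation, the excitatory list passed without poly(I:C) replicate 1 or saline replicate 3 (adjusted p = 0.0438 and 0.0444). Neuropeptides passed without poly(I:C) replicate 2 or saline replicate 3 (adjusted p = 0.0287 and 0.0293). Of the lists above, oxidative stress genes passed without poly(I:C) replicate 1 (adjusted p = 0.0484). In all 9 arrays the camera adjusted p with an estimated correlation was 0.4335, 0.507 and 0.348 for these lists in that order.

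Across the 45 lists, 7 were higher and 9 lower in 13 arrays, 0 with an estimated correlation and 14 by the exact permutation test after adjustment. Other splits of the 13 samples gave at least 16 lists in 7 of 100 cases, the real split included, and for the 9 lists of the 9 arrays in 18 of 100. In 9 arrays, 3 were higher and 6 lower, 0 with an estimated correlation and 0 by the exact permutation test after adjustment, where 12 had an unadjusted p under 0.05. The 126 splits there allow no p below 0.00794, at which a list alone cannot pass adjustment over 45 lists. That 0 is therefore weak evidence against the lists. The 6 lists called in both, with the same direction, are the ribosomal, complex I, complexes II to V, immediate early, heat shock and perineuronal net lists. The other 3 called in 9 arrays were lower in poly(I:C) there and were not called in 13. They are glucocorticoid-responsive genes at a median of -0.20 (camera adjusted p = 8.03e-05), myelin markers at -0.24 (adjusted p = 0.00474, against a median of 0.08 and adjusted p = 0.421 in 13 arrays, the other direction) and X-inactivation escape genes at -0.46 (adjusted p = 0.0106), with 0.346, 0.575 and 0.421 as the adjusted p with an estimated correlation. The myelin call rests on single arrays. It was lost without saline replicate 3 (median -0.09, adjusted p = 0.352), poly(I:C) replicate 1 (-0.17, adjusted p = 0.206) or saline replicate 2 (adjusted p = 0.0656), and the median was -0.59 without saline replicate 4 and -0.38 without poly(I:C) replicate 5. The saline libraries of the 9 arrays have low Y-linked levels throughout, and 3 of the 5 poly(I:C) libraries have high ones. In these, replicates 1, 3 and 4, the mean of the X-inactivation escape list was 12.43, 12.13 and 12.15. In poly(I:C) replicates 2 and 5 it was 12.78 and 12.74, against 12.78 to 12.92 in saline replicates 1 to 4. The call for this list thus went with the Y-linked level of the libraries. Cdkn1a, a cell cycle inhibitor that glucocorticoids induce, had an estimate of -1.48 ± 0.37 (SE) in 9 arrays, and Kdm6a, which escapes X inactivation, one of -0.51 ± 0.17.

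Of the lists camera did not call in 13 arrays, parvalbumin interneuron markers had a median of -0.26 in 13 arrays and -0.09 in 9, and dopamine and serotonin genes -0.14 and -0.03 (camera adjusted p = 0.0682 and 0.0657 in 13, and 0.359 and 0.214 as the adjusted p with an estimated correlation). Both passed the exact permutation test in 13 arrays (adjusted p = 0.04995 for each) and neither in 9 (adjusted p = 0.385 and 0.198). Lhx6, a transcription factor of these interneurons, had an estimate of -0.48 ± 0.13 (SE), and the serotonin receptor Htr2a one of -0.58 ± 0.17, neither past the threshold. Markers of tissue that a dissection can carry along did not pass. Their medians in 13 and in 9 arrays were -0.20 and -0.16 for striatal, 0.03 and 0.14 for septal, hypothalamic and thalamic, -0.08 and -0.06 for choroid plexus and -0.03 and -0.03 for ependymal markers (camera adjusted p from 0.0991 to 1.00 in 13 and from 0.21 to 0.949 in 9). The olfactory list had -0.0027 and 0.06, and its test leaned higher in both (adjusted p = 0.552 and 0.266), with Gng13 as its 1 member past the threshold. In the septal and in the olfactory list mean, 4 of 5 poly(I:C) arrays lay above all of saline replicates 1 to 4. The exact permutation p in 9 arrays was 0.0238 for each, and 0.119 after adjustment. Adjusted over the list alone, 3 olfactory members rose in 9 arrays. Medians were 0.05 and 0.06 for endothelial, -0.03 and 0.10 for pericyte, -0.0035 and -0.08 for meningeal and 0.04 and 0.11 for blood cell markers (adjusted p from 0.552 to 0.926 in 13 and from 0.252 to 0.945 in 9). They were -0.22 and -0.10 for deep-layer markers, 0.15 and 0.14 for upper-layer markers, -0.18 and -0.14 for GABA synthesis, -0.19 and -0.04 for GABA-A receptors and -0.15 and -0.05 for glycolysis (adjusted p from 0.0533 to 0.269 in 13 and from 0.0567 to 0.596 in 9). Chromatin regulators linked to autism had -0.10 and 0.05, circadian clock genes -0.06 and -0.06, synaptic scaffold genes -0.03 and 0.01, brain barrier carriers -0.03 and -0.02 and cholesterol synthesis 0.02 and -0.05 (adjusted p from 0.157 to 0.923 in 13 and from 0.0974 to 0.463 in 9). Adjusted over the list alone, 4 synaptic scaffold genes rose and 5 fell in 13 arrays. With 1 of the 9 arrays left out, the preset correlation alone called striatal, meningeal, upper-layer, GABA synthesis and chromatin lists in 1 or 2 cases each (adjusted p from 0.0138 to 0.0418). In the 9 arrays the adjusted p with an estimated correlation was 0.606, 0.971, 0.346, 0.421 and 0.421 for these lists.

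Immune lists did not pass in either comparison. Interferon-stimulated genes, the response that poly(I:C) evokes acutely, had a median of 0.02 over 36 members in 13 arrays (camera adjusted p = 0.189) and -0.05 in 9 (adjusted p = 0.473). Ifit3b had an estimate of 0.79 ± 0.20 (SE) in 13 arrays and 0.28 ± 0.18 in 9, while Isg15, which exceeded the negative-control median in 5 of 5 poly(I:C) and 4 of 8 saline arrays, had no determined size of difference. Medians were -0.01 for 47 cytokine, chemokine and receptor genes (adjusted p = 0.694), 0.06 for Toll-like receptor and NF-kB genes (adjusted p = 0.694), -0.02 for complement genes (adjusted p = 0.923) and 0.05 for MHC class I and antigen processing genes (adjusted p = 0.404). In 9 arrays these medians were -0.06, -0.0045, -0.02 and -0.0011 (adjusted p from 0.532 to 0.945), with the test leaning higher for the last 3. Of the cytokine list, 2 members fell over all genes and 4 adjusted over the list alone. These included Cx3cl1 and Il1r1, the receptor of interleukin-1, at -0.65 ± 0.15 in 13 arrays (adjusted p = 0.0476) and -0.73 ± 0.19 in 9.

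Within the libraries labelled female, 1 probe set passed, of 22206, and 2610 had an unadjusted p under 0.05. Stpg4 passed with an estimate of 1.54 ± 0.20 (SE, adjusted p = 0.0344) between 3 poly(I:C) and 4 saline libraries, but it exceeded the negative-control median in 0 of the 13 arrays, so it was not measured above background in either group. The next by p were Gm10373 at -0.98 ± 0.15, Matk, a kinase, at 0.86 ± 0.15, Snd1 at 1.04 ± 0.19 and Mllt6 at 1.2 ± 0.22, none past the threshold (adjusted p from 0.111 to 0.172). Gm10373 exceeded the negative-control median in 8 of 13 arrays and Snd1 in 4. The poly(I:C) libraries here include the 2 labelled female that carry Y-linked RNA. Without the 3 libraries that oppose their label, 0 passed and 1462 had an unadjusted p under 0.05, with 1 poly(I:C) library left in this contrast.

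Within the libraries labelled male, 1363 probe sets passed, 758 higher and 605 lower in poly(I:C), and 48 without poly(I:C) replicate 5. The smallest p-values belonged to Tnrc6c at -1.48 ± 0.17 (SE), Lpcat4 at -1.59 ± 0.19, Fabp7, a fatty acid binding protein of astrocytes, at 1.99 ± 0.24, the lipoprotein receptor Lrp1 at -1.24 ± 0.15 and the mitochondrial kinase Nadk2 at 1.63 ± 0.20 (adjusted p = 0.00299 for each). All 4 saline libraries of this contrast are replicates 5 to 8, so treatment and array set cannot be told apart in it. Fabp7 was at 15.27 ± 0.231 (SD, n = 5) in poly(I:C), 15.17 ± 0.224 (SD, n = 4) in saline replicates 1 to 4 and 13.21 ± 0.383 (SD, n = 4) in replicates 5 to 8. Lrp1 was at 11.30 ± 0.085, 11.31 ± 0.072 and 12.57 ± 0.156 in the same sets. Of its 2 poly(I:C) libraries, replicate 5 carries no Y-linked RNA. Without the libraries that oppose their label 1 poly(I:C) library was left, assumed to vary like the other groups, and limma called 0 (3817 unadjusted).

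The difference between the labelled sexes in the response to poly(I:C) passed for 118 probe sets, 76 with a higher and 42 with a lower estimate in males. The count was 0 to 2 on leaving out any 1 array other than saline replicates 4 (49) and 7 (126), and limma called 0 with array weights (3003 unadjusted). Rida differed by 2.01 ± 0.29 (SE), Cpq, a carboxypeptidase, by 1.62 ± 0.24, the junction protein Jam2 by 1.21 ± 0.18, Nadk2 by 1.72 ± 0.27 and Tpmt, a thiopurine methyltransferase, by 1.28 ± 0.21 (adjusted p = 0.0387 for each). Of the lists, 6 differed upward and 7 downward, and 0 with an estimated correlation. The largest medians were 0.80 for myelin markers and 0.66 for astrocyte markers (camera adjusted p = 0.000421 and 0.000232, with 0.665 and 0.454 as the adjusted p with an estimated correlation), while presynaptic vesicle genes stood at -0.36 (adjusted p = 0.0012, and 0.358 with an estimated correlation). This contrast also rests on saline replicates 5 to 8 as the male controls. Without the libraries that oppose their label, which leaves 1 poly(I:C) library of each labelled sex, limma called 0 genes (2506 unadjusted).

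Between the labelled sexes, with treatment as a term, 298 probe sets passed, 116 higher and 182 lower in males. Leaving out any 1 saline array gave 0 or 1, and leaving out poly(I:C) replicate 4 gave 3 and replicate 5 gave 1778. L1cam was higher by 1.21 ± 0.25 (SE), the kinase Lmtk3 by 1.03 ± 0.19, Fstl4 by 1.00 ± 0.24, and the defensins Defa3 and Defa17, which have identical values, by 1.00 ± 0.20. The defensins exceeded the negative-control median in 5 of 8 saline arrays, so the size of their difference is not determined. Gfap was lower by 1.45 ± 0.28, Ppp1r3c, a regulator of glycogen synthesis, by 1.32 ± 0.28, Fabp7 by 1.27 ± 0.27, Tnfaip6 by 1.2 ± 0.27 and Nadk2 by 1.12 ± 0.24 in labelled males (adjusted p from 0.0454 to 0.0484 for the 10). All saline males are replicates 5 to 8, so sex and array set cannot be told apart among the saline libraries. Gfap was at 9.64 in these and 11.77 in saline replicates 1 to 4. In the poly(I:C) libraries with Y-linked RNA, replicates 1, 3 and 4, it was 11.22, 12.06 and 12.37. The Y-linked genes did not pass, with Uty at 3.77 ± 1.19, Eif2s3y at 3.24 ± 1.37 and Kdm5d at 1.98 ± 0.75 (adjusted p from 0.0929 to 0.193). Because 3 of 5 poly(I:C) libraries oppose their label, each labelled sex holds libraries with and without Y-linked RNA. The contrast of labels is therefore not a contrast of males with females by Y-linked level. Each of these genes exceeded the negative-control median in 7 of 13 arrays, those with Y-linked RNA, so these sizes are not determined either. With a batch term for saline replicates 5 to 8, limma called 0 genes (1240 unadjusted), and within the 5 poly(I:C) libraries it also called 0 between labelled males and females (891 unadjusted). In both cases the poly(I:C) libraries alone set the sex difference. Their labelled males and labelled females each mix libraries with and without Y-linked RNA, so neither 0 tells whether the sexes differ.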

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

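The tests on why saline replicates 5 to 8 stand apart, on the origin of the opposed sex labels and on ribosomal genes within 9 arrays were chosen after the results were seen. The tests with a spike-in or a Y-linked term, on the spread among libraries and on splits of the 9 arrays had their bounds written before their values were computed, but they use the 9 arrays, a comparison chosen after the data were seen. The rules that turn values into verdicts on neighbouring regions, on a mixture, on ribosomal genes in 9 arrays and on the spread were revised after their values were seen. The splits of the 13 samples were written first, and those that keep saline replicates 5 to 8 together were added after the results were seen.

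Saline replicates 5 to 8 stand apart from the other 9 arrays on the first component. Male sex is argued against as the whole reason, because 0 of the 3 poly(I:C) libraries with Y-linked RNA lie in the component range of these 4 arrays. The spike-in controls, which are not part of the tissue, differ with an exact permutation p of 0.0014, so separate processing of these 4 arrays is a candidate explanation. Of 3 lists for neighbouring regions, 0 passed between saline replicates 5 to 8 and 1 to 4, but medians over members that go both ways do not exclude a difference in dissection. A difference between the animals themselves stays open too, since all 4 are saline males.

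The mean level of Y-linked genes was 8.635 in poly(I:C) replicate 3 and 8.371 in replicate 4, both labelled female, against at most 3.27 in the saline females. A changed order among the 5 poly(I:C) libraries alone is argued against, because the number with Y-linked RNA exceeds the number labelled male by 1. An exchange with saline would need a saline library out of place, and 0 oppose their label. A partial mixture of male and female tissue is not excluded for replicates 3 and 4. The lower of them is 0.2765 above the lowest male saline library, but below the 8.81 of poly(I:C) replicate 1. Uty was 9.07 and 9.21 in replicates 3 and 4, below every library labelled male that carries Y-linked RNA (lowest 9.24). Eif2s3y was 9.65 and 9.69 there, above every saline library labelled male (highest 9.11). Kdm5d was 7.18 and 6.21, against 6.42 to 7.40 in libraries labelled male with Y-linked RNA. The Y-linked genes thus did not all point the same way. The X-inactivation escape list averaged 12.13 and 12.15, below saline replicates 5 to 8 (12.37 to 12.49) and not toward the 12.78 to 12.92 of 1 to 4. Wrong labels or an exchange with samples outside the series may remain, and no biological explanation was tested.

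Ribosomal protein genes were higher in poly(I:C). The separate processing of saline replicates 5 to 8 is argued against as the whole reason by the 9 other arrays (exact permutation p = 0.03968, chosen after the result and 0.162 after adjustment over the lists). With the Y-linked level as a term, the difference in 9 arrays was 0.524 ± 0.222 (SE), 2.361 standard errors, past the bound set in advance. Poly(I:C) replicates 2 and 5, without Y-linked RNA, had list means of 14.72 and 14.91, against 14.19 to 14.37 in saline replicates 1 to 4. This argues against sex as the whole reason, but it rests on few libraries and no p-value was computed. With the spike-in level as a term the difference went from 0.488 to 0.306 ± 0.169 (SE), 1.811 standard errors, between the bounds set in advance, so array processing within the 9 arrays and maternal poly(I:C) cannot be told apart here. Prenatal poly(I:C), litter and dissection stay open as untested.

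For the 200 gene calls of 13 arrays, 1 of 100 free splits, the real one, gave as many, and the highest other gave 1, but only 10 of the 100 keep saline replicates 5 to 8 in the group of 8. Among 100 splits that all keep them there, again 1, the real one, gave as many, and the highest other gave 10. The fit keeps labelled sex as a term, but these splits do not all keep the 2 poly(I:C) libraries labelled male together. How males are set against saline replicates 5 to 8 therefore differs from the real split. So they cannot decide whether a random grouping of the other 9 arrays explains this count. Nor does the count single out treatment among what differs between these libraries, and limma called 0 with the array set as a batch term (2295 unadjusted). Within labelled females the real split gave 1 gene and the highest of the other 34 gave 0, which says nothing about treatment because that gene, Stpg4, was above background in 0 arrays. Between the labelled sexes the real split gave 298 genes, 1 of 100 splits as many, and the highest other, 245, came from a group of 6 with 0 of saline replicates 5 to 8, so that split follows the array set. For the lists, 7 of 100 splits gave at least the 16 of 13 arrays (highest other 19), and 18 of 100 at least the 9 of 9 arrays (highest other 16), so chance is not excluded for either count.

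In 96 groups examined for an array far from its group, 3 had one, and chance gives about 1 in 20. Chrm4 was at 9.809 in poly(I:C) replicate 2 and between 8.162 and 8.592 in the other poly(I:C) libraries. The heat shock list mean was 11.04 in saline replicate 5 and at least 11.22 in the other saline libraries. The median of negative controls was 5.192 in poly(I:C) replicate 5 and at most 4.958 in the others of its group.

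The response to poly(I:C) differed between the labelled sexes by 2.005 for Rida, 1.623 for Cpq, 1.21 for Jam2, 1.718 for Nadk2 and 1.284 for Tpmt. In males the estimates were 1.64, 1.17, 1.01, 1.63 and 1.23, and in females -0.36, -0.45, -0.20, -0.09 and -0.06. Saline replicates 5 to 8 lay below 1 to 4 for all 5, by -1.60, -1.43, -1.06, -1.77 and -1.24, and treatment and array set cannot be told apart for them.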

How the results depend on the processing

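Settings that use the array set of saline replicates 5 to 8, the Y-linked level or the libraries that oppose their label, and all 9-array settings, were chosen after the data were seen. Where a count moved, the cause was not tested unless stated. The 200 genes of poly(I:C) against saline became 0 with only saline replicates 1 to 4 (1877 at an unadjusted p under 0.05), with the array set as a batch term (2295), with the Y-linked level and batch term (1600), with no sex term (3536), with the replicate number as a block (2105) and without the libraries opposing their label (2321), all by limma. They became 85 with array weights, 534 with the filter at the 33rd percentile (fewer genes tested), 663 at an adjusted p of 0.1, 669 with the Y-linked level in place of sex, 723 with a trended robust prior, 886 with the first residual component, 3588 with only saline replicates 5 to 8 and 3631 at an unadjusted p of 0.05 and a fold of 1.2. Leaving out 1 array gave 36 to 512: 512, 123, 50 and 36 without poly(I:C) replicates 2, 3, 4 and 5, and 89, 109, 101, 106, 78 and 90 without saline replicates 1, 2, 4, 5, 6 and 8. The 1 gene within females became 0 with array weights (2629), the filter (2228) or without opposing libraries (1462), 89 with the robust prior and 2610 unadjusted. Leaving out 1 array gave 0 to 2: 2 without poly(I:C) replicate 2, 1 without saline replicates 5 and 6, and 0 without any other array, including arrays outside this contrast that share its variance. The 1363 within males became 0 without opposing libraries (3817), 623 with weights, 2068 with the filter, 2188 with the robust prior, 2429 at 0.1 and 4777 unadjusted, and 48 to 1368 with 1 array left out (48 without poly(I:C) replicate 5; 725, 625 and 670 without saline replicates 5, 6 and 8). The 118 of the interaction became 0 with weights (3003) or without opposing libraries (2506), 443 with the filter, 513 at 0.1, 684 with the robust prior and 3498 unadjusted. With 1 array left out it was 0 to 126, at 126 without saline replicate 7, 49 without saline replicate 4 and at most 2 without any other. The 298 between labelled sexes became 0 with a batch term (1240), no treatment term (4462) or the replicate block (1156), 126 after quantile normalization again, 863 with the filter, 1191 with the robust prior, 1558 at 0.1, 1881 with weights, 1985 without opposing libraries and 4436 unadjusted with the fold. With 1 array left out it was 0 to 1778: 680, 834, 3 and 1778 without poly(I:C) replicates 1, 3, 4 and 5, 1 without saline replicate 5 and 0 without any other saline array. With the batch term Eif2s3y went to -1.31, Kdm5d to -0.52 and Uty to -0.18 (adjusted p from 0.979 to 0.996), where poly(I:C) libraries alone set the sex difference. The 16 lists became 9 with only saline replicates 1 to 4 or a batch term and 0 with an estimated correlation, and stayed at 15 to 19 with 1 array left out. Without poly(I:C) replicate 5, glutamate receptor, presynaptic and somatostatin lists lost their call (adjusted p = 0.173, 0.148 and 0.351), the last also without poly(I:C) replicate 4 or saline replicates 4, 6 or 8 (adjusted p from 0.0508 to 0.0843). The 9 lists of the 9 arrays became 0 with an estimated correlation or by exact permutation, where 126 splits allow no p below 0.00794. They became 9 to 14 with 1 array left out, 14 without saline replicate 3. With the spike-in level as a term they became 11, and 8 of the 9 kept their call. The myelin call among them was lost without poly(I:C) replicate 1, saline replicate 2 or saline replicate 3 (adjusted p = 0.206, 0.0656 and 0.352). The 13 interaction lists became 5 by fry, 0 with an estimated correlation and 6 to 19 with 1 array left out, 7 and 6 without poly(I:C) replicates 2 and 5. Of the 30 named genes of the treatment comparison, all 30 kept direction and call after median centring, the robust prior and the Y-linked level in place of sex, and all 30 kept direction but lost the call in the 6 settings with 0 genes. Correlations of deviations between arrays of the same replicate number, from -0.118 to 0.068, give no sign that the number pairs them. In simulated data 64% of changes of 1 were recovered and 2% of 0.3, so a missing call does not exclude a small change. The simulated noise was independent between arrays and held no array-set difference, so these rates need not hold for the measured arrays.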

Other observations

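The 9-array values and the test on the spread among libraries belong to a comparison chosen after the data were seen, and Zbbx was singled out after its values were seen.

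Zbbx lay between 7.41 and 7.88 in the poly(I:C) arrays and between 6.23 and 7.06 in the 8 saline arrays, with an estimate of 0.95 ± 0.15 (SE) in 13 arrays and 1.02 ± 0.16 in 9. In the 9 arrays it did not pass (limma adjusted p = 0.534).

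The poly(I:C) libraries lay at a mean distance of 0.322 ± 0.0174 (SD, n = 5) from their centre, against 0.303 ± 0.0156 (SD, n = 4) in saline replicates 1 to 4 (exact permutation p = 0.127). Greater variation between animals after prenatal poly(I:C) was asked about. The p above the threshold does not bound the difference, so the bound written in advance was wrong in taking it as evidence against, and the question stays open.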
